A study of Mus musculus with 8 samples.

How the data were processed

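m6A-eCLIP libraries of αTC1-6 cells were analysed from the single deposited table, which holds whole-number read counts per site for 8 libraries. Per the submitters' processing notes, UMI-tools, cutadapt and STAR were among the tools and mm10 was the genome build. Versions, the way sites were called, the window over which reads were counted and any filter on sites are not given in the sources used here. UMI-tools handles molecular identifiers, but whether these counts are of unique molecules is not stated. Per the file headers, each column is 1 library with 1 site list shared by all, and the deposited counts are not normalized, since each column is whole and has its own total. Per the labels' protocols, an antibody against m6A was crosslinked with ultraviolet light, complexes were run on a gel and transferred to a membrane, and adapters were ligated before reverse transcription.

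Of 33774 sites, 33724 were 1 base long, 49 were 3 bases and 1 was 2 bases. Names came from RefSeq gene spans of the same assembly: 31927 sites (94.5%) had 1 name, in 6531 genes with a median of 3 sites. Where a site lay in the spans of several protein-coding genes (1272 sites) or of no gene (561), it stayed unnamed, and 1065 named sites also lay in another gene's span. Strand, exons and genome sequence were not used here, so a site cannot be placed in an exon, intron or untranslated region, overlapping antisense genes cannot be told apart, and the planned classes by transcript region and sequence motif were replaced by classes of gene overlap. The table had 124 mitochondrial sites and 0 unused columns.

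Counts were tested with edgeR 4.0.16 (filterByExpr, TMM scaling, quasi-likelihood F-test) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. M14KD was compared with SCR within the IP libraries and within the Input libraries. The change of IP over Input between M14KD and SCR (the interaction) and IP over Input within each genotype were contrasts of 1 model of all 8 libraries. The same fits were made on counts summed over the sites of each gene. Without the counting window, it is not known whether a read was counted at several neighbouring sites and so entered a sum more than once. Standard errors are the absolute log2 fold change over the square root of the F value. Of 19 gene lists, the 16 with at least 5 measured genes were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with an estimated correlation and fry beside it. The gene-level Input fit, the groups of sites by enrichment and the correlation of IP with Input changes were added after the data had been seen. For these groups, sites had a mean count of at least 20 and a prior count of 2. Bootstrap intervals used 10000 resamples.

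Groups, tests, gene lists, the alternatives not described as added and the rule for naming sites were fixed before the data were examined. The rule took, among called sites whose M14KD libraries both lay on 1 side of both SCR libraries, 1 site per gene (lowest p), the 10 largest falls and 10 largest rises for IP, and 5 each way for Input and the interaction, filled to 5 by unadjusted p with values only. For IP over Input it took the 5 largest called fitted folds in each genotype. Mettl14, Gcg and Mettl3 were always included, as were list members passing at gene level, of which there were none. The result of 1 named IP site is not reported here. Alternatives were DESeq2 1.42.0, other scalings (DESeq2 size factors, column totals, or the 25% of features with the lowest IP over Input), no filter or a mean count of at least 20, all 8 libraries in 1 model, each replicate left out, and the replicate number as a block.

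Input libraries held fewer counts than IP libraries, and the median SE of a site's log2 fold change was 0.14 in IP, 0.25 in Input and 0.30 in the interaction. All scalings use site counts alone. Reads outside the sites were not analysed here, so a loss that is equal at all sites cannot be seen. The chi-square over degrees of freedom of replicate pairs was 1.35 to 2.55 against sampling noise alone. Library preparation can add such spread within 1 culture, so this does not show separate cultures, and each library entered the tests as labelled. The IP libraries of SCR replicates 1 and 2 (2.55) were about as far apart as SCR replicate 1 and M14KD replicate 4 (2.50).

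Each test was checked on simulated counts drawn from the real means, library sizes and dispersions, with 200 features changed. For IP sites (33774 features), 50.7% of 1.5-fold, 95.5% of 2-fold and 100% of 3-fold changes were recovered, and 5.2% of calls were false. Input sites gave 16.9%, 50% and 91.7%, with 4.95% false. For interaction sites 6.06%, 41.8% and 68.2% were recovered and 9.41% of calls were false, and for IP over Input in SCR 38.8%, 68.7% and 89.4%, with 5.07% false. At gene level (6531 features) 2-fold changes were recovered at 94% in IP, 76.9% in Input, 76.1% in the interaction and 71.6% for IP over Input, with 8.54%, 3.42%, 10.1% and 7.24% of calls false. Intervals of the site interaction with 4 degrees of freedom covered 99.4% of the simulated values, so they are wider than their nominal 95%. In 10 simulations in which the amino acid list was shifted by -0.15 with genes drawn independently, camera with the preset correlation called it in 10, called another list in 3 of 149 tests, and with an estimated correlation called it in 0. Figures were drawn with matplotlib 3.10.9.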

Results

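The m6A mark, a methyl group on adenosine that is the most common internal modification of messenger RNA, was mapped by m6A-eCLIP in αTC1-6, an established mouse pancreatic alpha cell line that makes glucagon. In this assay an antibody against m6A is crosslinked to RNA with ultraviolet light, and reads are counted at the crosslinked sites. The immunoprecipitated libraries (IP) were set beside Input libraries, which measure the RNA before the antibody selects. Cells had received a scramble siRNA (SCR) or an siRNA against Mettl14 (M14KD), the partner of Mettl3 in the enzyme that writes m6A on messenger RNA. Each of the 4 groups held 2 libraries, SCR replicates 1 and 2 and M14KD replicates 3 and 4, and the IP and Input libraries shared these numbers. The table held counts at 33774 sites, of which 31927 lay in the span of 1 named gene, in 6531 genes. Summed site counts ran from 3438530 to 3637740 in the Input libraries and from 10207383 to 10918559 in the IP libraries. The median count per site was 31 to 34 in Input and 162 to 177 in IP. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these samples.

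Mettl14, the knockdown target, had lower counts in both M14KD libraries of each kind. Its 2 sites on chromosome 3, at positions 123368535 and 123369542 of mm10, were summed. Input counts were 64 and 44 in SCR and 32 and 22 in M14KD, or 14.9 ± 3.96 and 7.63 ± 1.74 CPM (counts scaled to the summed site counts of a library; SD, n = 2), so that M14KD held 51.2% of the SCR level. IP counts were 78 and 81 in SCR and 42 and 25 in M14KD, 43.4% of the SCR level. The edgeR log2 fold changes were -0.96 (SE 0.27, adjusted p = 0.26) in Input and -1.17 (SE 0.24, adjusted p = 0.156) in IP, neither past the threshold over all genes, although the IP value passed without replicate 1, without replicate 2 and without replicate 3, each of which left a group with 1 library. Among the 7 measured genes of the fixed m6A writer list, Mettl14 alone passed in IP when adjusted over the list alone. Wtap (0.16, SE 0.08) and Virma (0.09, SE 0.08), other subunits of the writer complex, had IP log2 fold changes that did not pass. Of the 7 genes 3 had values above 0 and 4 below. Among those below, 2 had an unadjusted edgeR p under 0.05, Mettl14 and Pcif1. Mettl3 had no site in the table. Gcg, the glucagon gene, had 49959 ± 2256 CPM over its 23 sites in SCR Input and 57690.3 ± 412 in M14KD Input, and 12552 ± 670.4 and 15133 ± 158 CPM in IP (SD, n = 2). Its gene-level log2 fold changes were 0.21 (SE 0.05, adjusted p = 0.219) in Input and 0.29 (SE 0.06, adjusted p = 0.191) in IP. Sums over sites may count a read more than once.

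**Figure D1:**
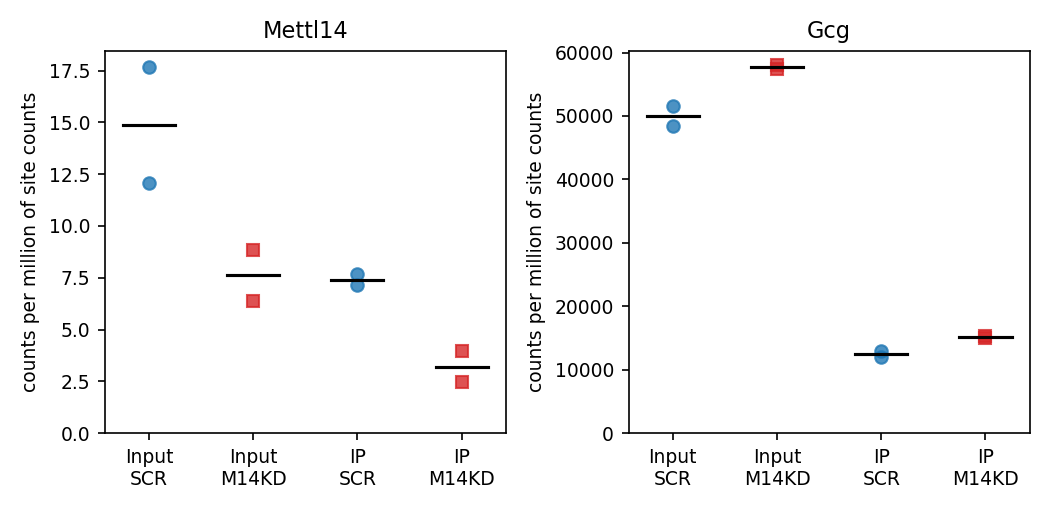
Counts of Mettl14 and Gcg summed over their sites, in CPM, for each library (circles SCR, squares M14KD) with the group mean as a line. Both M14KD libraries lie below both SCR libraries for Mettl14 and above them for Gcg, in Input and in IP.

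The first comparison asked which sites gained or lost reads in the IP libraries after Mettl14 knockdown, without taking off the Input change. Slc7a5, a large neutral amino acid transporter, had 14 of 15 tested sites lower in the M14KD IP libraries, and Peg10, an imprinted gene derived from a retrotransposon, had 22 of 61. Sites of a gene are not independent: 72.6% of sites had another within 100 bases, and neighbours may count the same reads. With 1 site kept per 100 bases, 22 sites in 14 genes were called. Each gene was named at its called site with the lowest p, which is not always its largest change. At these sites log2 fold changes were -0.93 (SE 0.21) in Atf3, a stress-induced transcription factor, -0.80 (SE 0.18) in Slc6a9, a glycine transporter, and -0.79 (SE 0.11) in Vgf, a secretory granule protein. Sites in Scg2, another granule protein, rose at 17 of 22 tested positions, and all 7 tested sites rose in Ttr, which encodes the thyroid hormone carrier transthyretin. At the called site with the lowest p, the IP over Input log2 ratio in SCR was -1.30 in Scg2 and -1.91 in Ttr. It was 1.61 in Slc7a5 and 2.83 in Peg10. A ratio below 0 means fewer IP than Input reads with TMM scaling, so an IP change there is not by itself a change of m6A.

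In all, edgeR's quasi-likelihood test called 210 of 33348 sites at a Benjamini-Hochberg adjusted p threshold of 0.05, 85 higher in 38 genes and 125 lower in 39 genes, of which 9 sites had no single gene name. Unadjusted p values under 0.05 numbered 4426, against 1667.4 by chance alone. The Vgf site at position 137031547 of chromosome 5 went from 40.1 ± 0.11 to 23.2 ± 0.32 CPM (SD, n = 2; adjusted p = 0.00776). The Atf3 site at position 191170628 of chromosome 1 went from 7.62 ± 0.45 to 3.99 ± 0.36 (adjusted p = 0.0439), and the Slc6a9 site at position 117868229 of chromosome 4 from 12.6 ± 2.42 to 7.18 ± 0.53 (adjusted p = 0.0427). Map4, a microtubule-associated protein, fell by 0.75 (SE 0.16), and Trib3, a pseudokinase of the integrated stress response, by 0.70 (SE 0.12). Pik3r2, a regulatory subunit of phosphoinositide 3-kinase, decreased by 0.69 (SE 0.14), and Scd2, a fatty acid desaturase, decreased by 0.69 (SE 0.10). Pdia4, a disulfide isomerase of the endoplasmic reticulum, and Hcn2, a cation channel, each dropped by 0.68 (SE 0.12) at the named site. Summed over its sites, Pdia4 had a gene-level log2 fold change near 0, given with its list below. The IP over Input log2 ratio in SCR was below 0 at the named sites of Map4 (-0.89), Pik3r2 (-0.86), Hcn2 (-0.84) and Scd2 (-0.67). It was above 0 at those of Trib3 (1.36), Vgf (1.12), Atf3 (0.62), Slc6a9 (0.19) and Pdia4 (0.04). Further genes with several lower sites were Irs2, the insulin receptor substrate, with 5 of 68, Pck2, mitochondrial phosphoenolpyruvate carboxykinase, with 5 of 11, Reep6 with 5 of 16, Sesn2 with 4 of 12, and asparagine synthetase, Asns, with 3 of 7. Genes singled out by their number of called sites, and list members that did not pass, were chosen after their values were seen.

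Among the sites that rose, Eny2, a factor of transcription and mRNA export, rose by 0.92 (SE 0.20, adjusted p = 0.0421), from 4.15 ± 0.06 to 7.87 ± 0.10 CPM at position 44432445 of chromosome 15. B3galnt1, a glycosyltransferase, rose by 0.71 (SE 0.16), Rbbp8, a DNA repair factor, by 0.69 (SE 0.15), and Kctd1 by 0.61 (SE 0.11), the last at a position that also lies in the spans of 4933424G05Rik and Mrpl27-ps. The uncharacterised 1600012H06Rik rose at 7 of 9 tested sites, with 0.56 (SE 0.11) at its named site. Tceal8 (0.55, SE 0.13), 1810037I17Rik (0.54, SE 0.13), the exon junction factor Magoh (0.53, SE 0.10), the calcium-binding protein S100a4 (0.53, SE 0.10) and the imprinted zinc finger gene Zim1 (0.52, SE 0.10) completed the named set. Called sites were 1 of 44 tested in Zim1, 1 of 9 in B3galnt1 and Rbbp8 each, and 1 of 5 in Kctd1. They were 1 of 3 in Tceal8 and 1810037I17Rik each, 1 of 2 in Magoh, 2 of 2 in S100a4 and 1 of 1 in Eny2. The IP over Input log2 ratio in SCR was below 0 at the named sites of Eny2 (-2.67), 1810037I17Rik (-1.86), B3galnt1 (-1.68), Tceal8 (-1.65), Kctd1 (-0.99) and S100a4 (-0.78). It was above 0 at those of 1600012H06Rik (1.69), Zim1 (1.16), Rbbp8 (0.48) and Magoh (0.10). Without M14KD replicate 3 no site was called, without SCR replicate 1 the count was 1422, without M14KD replicate 4 it was 80, and DESeq2 called 118. Fold changes of sites within 10 bases of each other correlated at 0.926, and with 1 site kept per 100 bases 22 sites were called; higher sites made up 40.5% of calls, 27.1% when libraries were scaled by column totals only, and 50% with DESeq2 and without M14KD replicate 4. Without SCR replicate 1 the balance turned, with 946 higher and 476 lower, so an excess of falls does not hold in every setting.

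**Figure D2:**
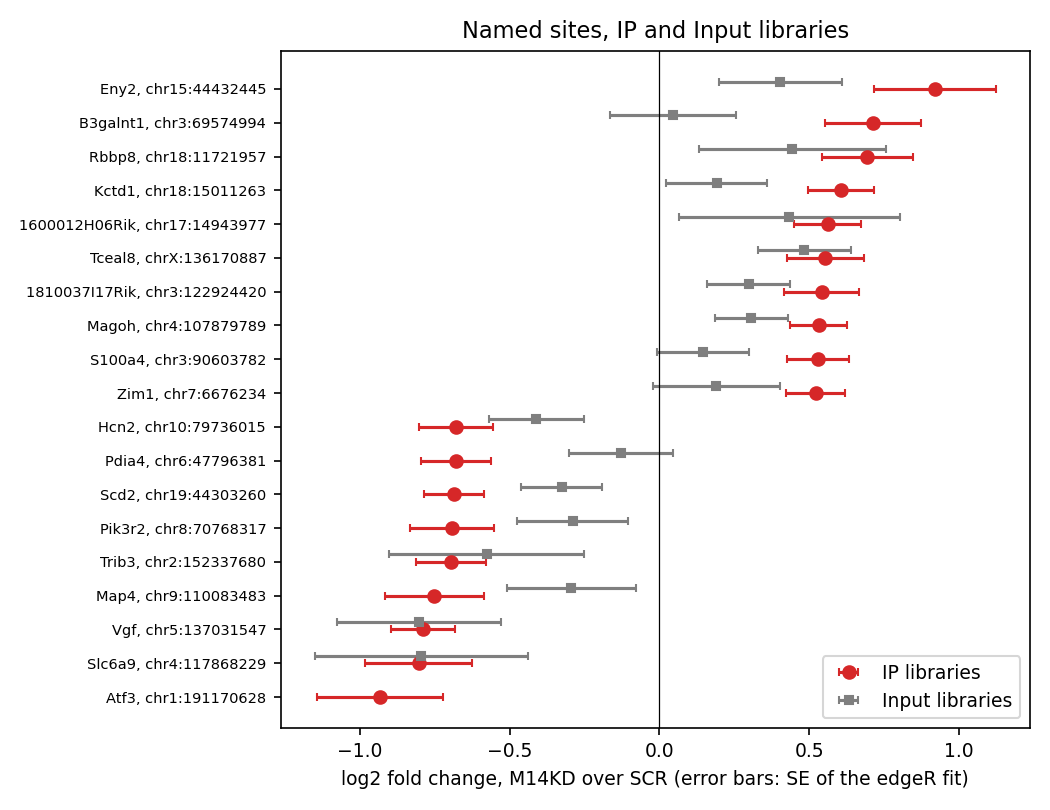
Log2 fold change of M14KD over SCR at 19 named sites, in the IP libraries (circles) and the Input libraries (squares), with the SE of the edgeR fit as bars. The IP values run from -0.93 at Atf3, which had too few Input counts to test, to 0.92 at Eny2, and the Input value has the sign of the IP value at the other 18 sites.

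Counts were also summed over the sites of each gene, and no gene passed the threshold among 6381 tested by edgeR, with 900 at an unadjusted p under 0.05 (319.05 by chance) and 45 called by DESeq2. The lowest adjusted p was 0.0612, of Vgf, which passed under 3 other scalings. Without SCR replicate 1 the count was 182, without SCR replicate 2 it was 19, without M14KD replicate 3 it was 11 and without M14KD replicate 4 it was 169.

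Gene lists fixed in advance were tested on these gene-level values with camera. Members were also adjusted within their own list alone, with no correction across lists. Members said below to have risen or fallen passed only that adjustment, and by edgeR none passed over all genes. The amino acid transport and metabolism list was lower in the M14KD IP libraries (22 measured genes, median log2 fold change -0.16, adjusted p = 0.000143). This call did not hold with an estimated correlation between genes (adjusted p = 0.798) or with fry, a rotation test (adjusted p = 0.314). With an estimated correlation, camera called a simulated shift of -0.15 in 0 of 10 simulations, so it cannot decide on a shift of this size. Those simulations drew genes independently, so they do not back the preset correlation of 0.01, and fry was not simulated. The estimated correlations were 0.05 for this list, 0.17 for stress response, 0.11 for insulin signalling and 0.39 for splicing. Adjusted over the list alone, 6 of its genes fell and 1 rose. Slc7a5 fell by 0.56 (SE 0.08), Gpt2, an alanine aminotransferase, by 0.47 (SE 0.12), Asns by 0.39 (SE 0.07) and Slc7a1, a cationic amino acid transporter, by 0.36 (SE 0.09), and Got1 and Shmt2 were the other 2, while Mat2a, which makes the methyl donor S-adenosylmethionine, rose by 0.33 (SE 0.09). The unfolded protein and integrated stress response list was also lower (24 genes, median -0.12, adjusted p = 0.000109), and this call did not hold either (adjusted p = 0.798 with an estimated correlation, adjusted p = 0.314 with fry). Its median was -0.03 without replicate 2. Its members that fell, adjusted over the list alone, were 4: Atf3 by 0.73 (SE 0.13), Trib3 by 0.64 (SE 0.10), the glutathione-degrading enzyme Chac1 by 0.57 (SE 0.09) and the stress-induced mTOR regulator Sesn2 by 0.40 (SE 0.08). Hspa5 (0.23, SE 0.08) and Pdia4 (0.00, SE 0.07), chaperones of the endoplasmic reticulum on the same list, did not pass.

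The insulin, IGF and mTOR signalling list was lower as well (22 genes, median -0.12, adjusted p = 0.00947), a call that did not hold with an estimated correlation (adjusted p = 0.798) or fry (adjusted p = 0.314). Its median was -0.05 without replicate 3 and -0.21 without replicate 4. Pik3r2 fell by 0.60 (SE 0.12), the translation repressor Eif4ebp1 by 0.38 (SE 0.09), the kinase Mtor by 0.34 (SE 0.08) and its partner Rptor by 0.32 (SE 0.10), adjusted over the list alone. The splicing and polyadenylation list was higher (23 genes, median 0.12, adjusted p = 0.0144), with 18 of 23 values above 0, although no member passed when adjusted over the list alone. It did not pass with an estimated correlation (adjusted p = 0.828) or fry (adjusted p = 0.586), and its median was 0.25 without replicate 1 and 0.06 without replicate 2. Srsf3, a splicing factor, had a log2 fold change of 0.45 (SE 0.12). The insulin list lost its call without replicate 1 (adjusted p = 0.0733), both the insulin and the splicing list without replicate 3 (adjusted p = 0.1 for each), and the splicing list without replicate 2 (adjusted p = 0.642).

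The other lists did not pass as lists. Of 18 measured alpha cell identity genes (median 0.01, adjusted p = 0.567), Gcg and Ttr (0.42, SE 0.06) passed as higher and Peg10 as lower, by 0.48 (SE 0.10), adjusted over the list alone. Over all genes Gcg had adjusted p = 0.191 by edgeR in IP, and none of its 23 sites was called there. Of 23 secretory granule genes (median -0.03, adjusted p = 0.567), Scg2 rose by 0.42 (SE 0.06) and Vgf fell by 0.80 (SE 0.09). Of 17 immediate early genes (median -0.04, adjusted p = 0.45), Jund fell by 0.31 (SE 0.07) and Nr4a1 by 0.61 (SE 0.16). Of 7 ribosomal protein and elongation factor genes (median 0.06, adjusted p = 0.631), Rpl37a rose by 0.33 (SE 0.09), while Eef1a1 fell by 0.38 (SE 0.08) and Eef2 by 0.20 (SE 0.07). No member passed in the lists of 9 m6A erasers and readers (median 0.08, adjusted p = 0.431), 13 ion channels and receptors (median -0.05, adjusted p = 0.809), 25 cell cycle genes (median 0.05, adjusted p = 0.863), 38 chromatin regulators (median -0.06, adjusted p = 0.193), 7 mitochondrially encoded genes (median 0.05, adjusted p = 0.567), 5 long noncoding RNAs (median 0.07, adjusted p = 0.567) or 5 interferon response genes (median 0.02, adjusted p = 0.779). The m6A writers had a median of -0.12 (adjusted p = 0.131). The ribosomal list had a median and mean above 0 (0.04 for the mean) and a camera direction below it, and the ion channel list had a median below 0 and a mean of 0.05. Markers of other islet cells had 2 measured genes, replication-dependent histones 1 and markers of non-endocrine cells 0, too few to test.

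**Figure D3:**
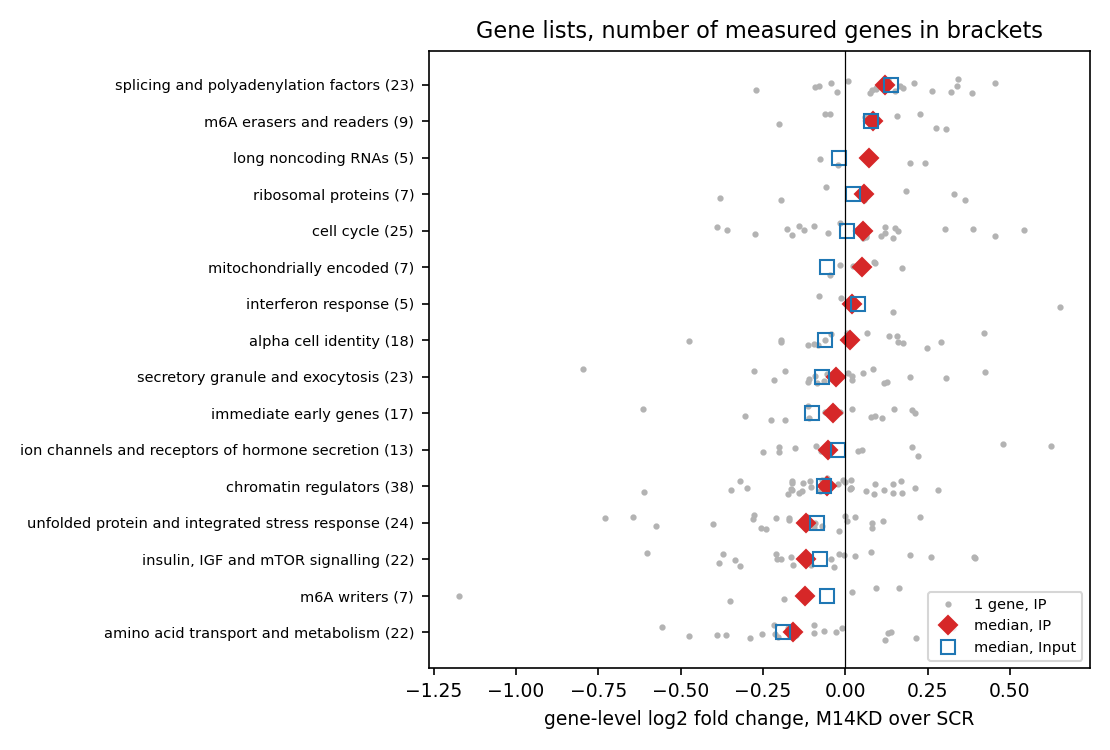
Gene-level log2 fold change of M14KD over SCR for the 16 tested lists, with each gene's IP value as a dot, the IP median as a diamond and the Input median as an open square. The IP medians run from -0.16 for amino acid transport and metabolism to 0.12 for splicing and polyadenylation factors.

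The Input libraries showed which genes changed in RNA reads at the same sites. Sites in Jund, a subunit of the AP-1 transcription factor, fell at 4 of 15 tested positions, by 0.71 (SE 0.12) at the named one. Peg10 fell by 0.88 (SE 0.17), Slc7a5 by 0.78 (SE 0.16) and Lonp1, a mitochondrial protease, by 0.58 (SE 0.12), each at 1 site. Scg2 rose at 13 of 22 sites (0.52, SE 0.09) and Manf, a neurotrophic factor of the endoplasmic reticulum, at 3 of 7 (0.51, SE 0.10). Mkks, a chaperonin-like protein, rose by 0.77 (SE 0.16), the RNA-binding protein Hnrnpdl by 0.59 (SE 0.12) and 1810037I17Rik by 0.58 (SE 0.12), each at 1 site. Id2, an inhibitor of differentiation, rose at 2 of 14 sites and was named after its values were seen, as the remaining gene with a call. A Trib3 site had a log2 fold change of -1.63 (SE 0.35, adjusted p = 0.0529).

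In Input, edgeR called 28 of 30147 sites, 21 higher in 6 genes and 7 lower in 4, with 2620 at an unadjusted p under 0.05 (1507.35 by chance). Higher sites made up 75% of calls, 64.9% with libraries scaled on the 25% of features with the lowest IP over Input, and 50% without SCR replicate 1. At gene level edgeR called 0 of 5826 genes (594 at an unadjusted p under 0.05, 291.3 by chance) and DESeq2 23; edgeR called 34 without SCR replicate 1 and 2 (Peg10, Scg2) without SCR replicate 2. The number of called sites was 0 without M14KD replicate 3, 0 without M14KD replicate 4, 4 without SCR replicate 2 and 0 with no filter on low counts. The same 4 lists passed camera in the gene-level Input fit, in the same directions: amino acid transport and metabolism (median -0.19, adjusted p = 2.21e-07), stress response (-0.09, adjusted p = 0.0487), insulin, IGF and mTOR signalling (-0.08, adjusted p = 0.0341) and splicing (0.14, adjusted p = 0.0144). With an estimated correlation these had adjusted p = 0.616.

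The genes with called IP sites mostly had the same sign in Input. Among the 39 genes with a lower IP site, 38 had an Input test at that site and 37 of these were below 0, with a median Input log2 fold change of -0.35 (bootstrap 95% interval over genes -0.50 to -0.29). Mpped1 was the exception (0.12, SE 0.30). Among the 38 genes with a higher IP site 36 were above 0 in Input, with a median of 0.27 (0.21 to 0.31), and AA414768 and Cops2 were below 0. The median IP values at these sites were -0.55 and 0.45, which selection on the IP libraries makes larger. The median interactions there (the IP change beyond the Input change) were -0.16 (-0.28 to -0.08) and 0.19 (0.12 to 0.24), away from 0 on the side that the same selection favours. Across 5819 genes tested in both, the IP and Input log2 fold changes had a Pearson correlation of 0.44 and a Spearman correlation of 0.48. Genes are not independent replicates, and IP and Input libraries of 1 number may share a culture, so these correlations are descriptions. The Pearson value was 0.23 without SCR replicate 2 and 0.24 without M14KD replicate 3.

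**Figure D4:**
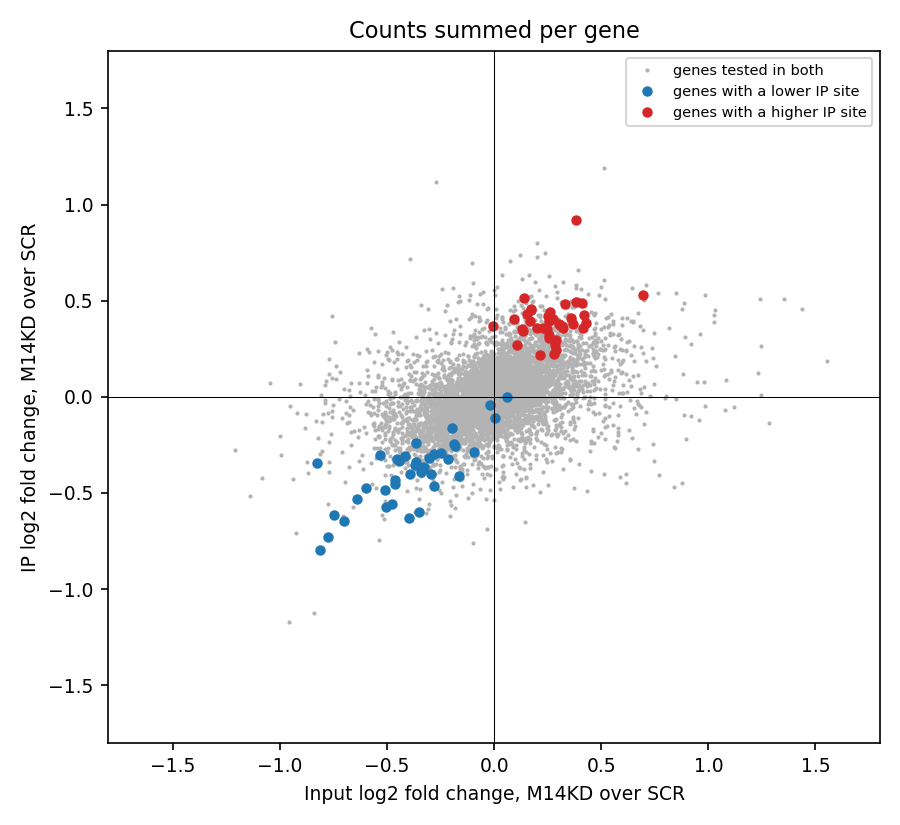
Gene-level log2 fold change of M14KD over SCR in IP (vertical axis) against Input (horizontal axis) for 5819 genes, with genes that hold a lower IP site in blue and a higher one in red. Most blue points lie in the lower left quadrant and most red points in the upper right, around a Pearson correlation of 0.44.

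The interaction asked whether the IP over Input ratio of a site differed between M14KD and SCR, which is the change in antibody-selected reads beyond that in RNA. No site passed among 33356. The named sites, chosen by their unadjusted p, therefore carry values only. Tenm4, a transmembrane protein, had an interaction of -2.25 (SE 0.46, adjusted p = 0.891), Mrps30, a mitochondrial ribosomal protein, -0.90 (SE 0.22), Ppp1r26 -1.79 (SE 0.47) and Lrpap1, a chaperone of lipoprotein receptors, -0.70 (SE 0.19). On the other side were the deubiquitinase Usp47 (1.79, SE 0.42), Atoh8, a basic helix-loop-helix transcription factor (1.19, SE 0.30), the ion channel subunit Lrrc8d (1.48, SE 0.39) and the hydrolase Adprhl2 (0.92, SE 0.26). Zfp846 had Input counts of 0 and 0 in SCR and 5 and 6 in M14KD, and Espnl 8 and 9 against 0 and 1, so the rule named both but their fitted values are no bounds. At gene level Mettl14 itself had an interaction of -0.23 (SE 0.38), which ran from -0.56 without replicate 1 to 0.06 without replicate 2, and Gcg one of 0.07 (SE 0.08).

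The edgeR interaction test gave 1242 sites at an unadjusted p under 0.05, against 1667.8 by chance, and a lowest adjusted p of 0.891. DESeq2 also called 0, and at gene level edgeR and DESeq2 called 0 of 6379 genes, with 168 at an unadjusted p under 0.05 by edgeR, against 318.95 by chance. With the replicate number as a block 1997 sites and 421 genes had an unadjusted p under 0.05, above chance, so on which side of chance these counts lie depends on the model. None of the 16 gene lists passed (lowest adjusted p = 0.313). With the block 1 site was called, in Atoh8 at position 72206776 of chromosome 6 (1.17, adjusted p = 0.00375), as it was without SCR replicate 2 (1.60, adjusted p = 0.000184). Its Input counts were 216 and 105 in SCR and 96 and 114 in M14KD, and its IP counts 266 and 256 against 496 and 281. The block also brought 2 lists past the threshold, alpha cell identity (median 0.09, adjusted p = 0.0341) and mitochondrially encoded genes (median 0.08, adjusted p = 0.0345), both with adjusted p = 0.892 with an estimated correlation. The median SE of a site's interaction was 0.30, and 65.1% of sites had a 95% interval above a 2-fold fall with 4 degrees of freedom. The share was 80.9% with the larger number that edgeR's moderated test uses. For a 1.5-fold fall the 2 shares were 28.3% and 50.1%.

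IP over Input within each group showed how the antibody ranked transcripts. Mitochondrially encoded transcripts were depleted, with all 7 measured genes lower in SCR (median log2 ratio -2.43) and in M14KD (median -2.37), and in SCR this held when libraries were scaled by column totals or on the 25% of features with the lowest IP over Input. Mitochondrial sites held 26.2% to 27.9% of counts in the Input libraries and 7.31% to 8.14% in the IP libraries. Relative to the average transcript, chromatin regulators were enriched, 25 of 38 higher and 3 lower in SCR, as were immediate early genes, 11 of 17 higher and 1 lower. Over all 6379 genes, 2245 were higher and 2214 lower in SCR, and no test of lists was run on this ratio. Splicing factors, with 15 of 23 lower, and secretory granule genes, with 15 of 23 lower, lay on the other side. Those last directions depend on the scaling: by column totals, 9 splicing genes were lower and 8 higher, and 10 granule genes lower and 9 higher, and on the 25% of features with the lowest IP over Input 14 of each list were higher. In M14KD the counts were 24 of 38 for chromatin regulators, 10 of 17 for immediate early genes, 15 of 23 for splicing and 13 of 23 for granule genes.

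Of 33356 sites, 11352 were higher and 11134 lower in IP than in Input in SCR, and 11261 and 11050 in M14KD, by edgeR at an adjusted p threshold of 0.05. The share of higher calls in SCR was 50.5% with TMM scaling, 77.9% by column totals and 92.5% on the 25% of features with the lowest IP over Input, which moved the median of all sites from 0.06 to 0.77 and 1.47 on the log2 scale. On the last scaling 15264 of the 22486 sites called in SCR kept the direction of their fold. The sites named for SCR have the largest fitted folds, but a fold over an Input count of 0 is known only as a lower bound and cannot be ranked. They were in Zfp846, whose IP count of 73 against 0 in Input made it at least 5.03-fold enriched over a floor of 3 counts per group, Hspa12a (at least 2.00-fold), Gm13524 (at least 1.72-fold), Zfp322a, in a span shared with 4930586N03Rik, at 24.9-fold (counting interval 6.82 to 207), and Sgo1 at 24.6-fold (4.33 to 979). In M14KD they were in Zfp446 (at least 5.67-fold), Arhgap29 (at least 5.60-fold), Brd1 (at least 2.49-fold), Sowahc at 31.6-fold (14.5 to 86.4) and Zfp865 at 32.6-fold (5.76 to 1295). The bounds over the floor leave out the error of the IP count. Lower limits of the counting interval, which include it, were 3.99 for Zfp846, 1.52 for Hspa12a and 1.30 for Gm13524. They were 4.51 for Zfp446, 4.45 for Arhgap29 and 1.92 for Brd1. In M14KD, where Input counts were above 0, edgeR did not call Zfp846 (1.78-fold, adjusted p = 0.085), Hspa12a (2.09-fold, adjusted p = 0.157) or Gm13524 (1.24-fold, adjusted p = 0.684). In SCR it did not call Brd1 (2.29-fold, adjusted p = 0.19), but called Zfp446 (3.12-fold) and Arhgap29 (8.51-fold). The 2 groups ranked sites alike, with a correlation of 0.94 across sites; 9947 sites were higher in both, 9936 lower in both and 1 opposite.

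Sites were ranked by their mean enrichment to ask whether strongly enriched sites lost more in M14KD. The median log2 IP over Input ratio of the highest 25% exceeded that of the lowest 25% by 2.61 ± 0.024 in SCR and by 2.64 ± 0.0025 in M14KD (SD, n = 2). The difference of 0.02 had an exact two-sided permutation p of 0.333, the smallest that 2 against 2 libraries allow.

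**Figure D5:**
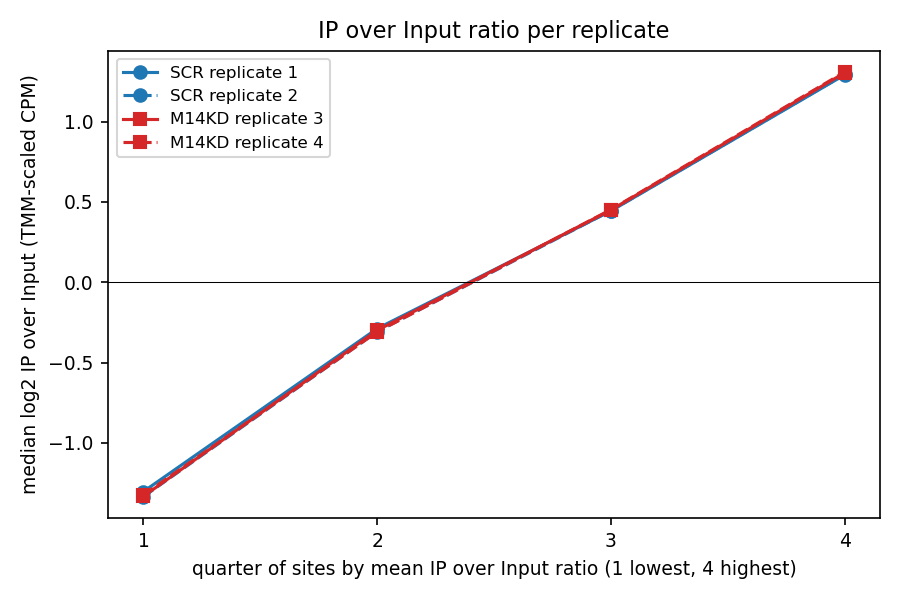
Median log2 IP over Input ratio (vertical axis) of 31921 sites in 4 equal groups by mean enrichment (horizontal axis), for each replicate number, with SCR in blue and M14KD in red. The 4 lines overlap, with differences between the highest and lowest group of 2.61 in SCR and 2.64 in M14KD.

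Changed IP sites were spread over the site classes without a detectable difference. Sites in 1 protein-coding gene were called in 200 of 31078 cases (0.644%, exact 95% interval 0.558 to 0.739), sites in several genes in 5 of 1271 (0.393%, 0.128 to 0.916), sites in no gene span in 4 of 483 (0.828%, 0.226 to 2.11), sites in 1 gene of another kind in 1 of 392 (0.255%, 0.00646 to 1.41) and mitochondrial sites in 0 of 124 (upper bound 2.93%). Fisher's exact tests gave adjusted p values from 0.69 to 1. By column totals 2 classes differed, and 3 did without SCR replicate 1; these intervals cover counting error only.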

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

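The alternatives with 1 site per 100 bases, without mitochondrial sites and with the span trend taken off, and every alternative of the gene-level Input fit, of the Input and blocked gene lists, of the groups by enrichment and of the correlation, were chosen after the data had been seen. Unless stated, the cause was not tested. All 210 called IP sites kept their direction in every setting in which they were tested. They were selected on these same libraries, so this agreement is no separate support. With DESeq2 118 IP sites were called, of which 105 were among the 210, and with 1 site per 100 bases 22, where fewer sites were tested. Input sites numbered 57 with the scaling on the lowest IP over Input, 0 without the filter, 49 at a mean count of at least 20 and 17 with 1 site per 100 bases. IP over Input gave 10551 sites in SCR and 10471 in M14KD with 1 site per 100 bases. Gene-level IP gave 1 gene (Vgf) with DESeq2 size factors, 1 with column totals and 1 with the scaling on the lowest IP over Input, 45 with DESeq2 and 11 with all 8 libraries in 1 model. Gene-level Input gave 1 (Scg2) with column totals, with the scaling on the lowest IP over Input, at a mean count of at least 20 and with all 8 libraries, and 23 with DESeq2. Of the 4 gene lists, 0 passed with an estimated correlation, 0 with fry and 0 in the interaction. Of the site classes, 2 differed by column totals.

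Leaving out each replicate gave 0 to 1422 IP sites, 0 to 40 Input sites, 0 to 1 in the interaction, 11 to 182 genes in IP, 0 to 34 in Input, 2 to 4 gene lists and 0 to 3 site classes, where a lone library is assumed to vary like the other groups. The Mettl14 gene-level interaction ran from -0.56 (without replicate 1) to 0.057 (without replicate 2). In the interaction the splicing list had a median of -0.0025 and the amino acid list one of 0.049.

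With the replicate number as a block, 1 site (Atoh8) passed in the interaction and 2 gene lists, neither among the 4, and the splicing and amino acid medians were 0.0029 and 0.051. The block raised the interaction's counts at an unadjusted p under 0.05 from 1242 to 1997 sites and from 168 to 421 genes. It moved no other count of calls beyond 1.5 times. For IP over Input it raised the called sites from 22486 to 23428 in SCR and from 22311 to 23224 in M14KD. All sites called there without the block were kept. Over the named sites and genes in each setting, 819 values kept direction and side of the threshold, 122 no longer passed and 53 newly passed, and 1 turned. The 819 include values that did not pass to begin with, such as those of Gcg and Mettl14 sites, so they do not measure how often calls held. At these depths, simulated 2-fold changes were recovered at 95.5% of IP, 50% of Input and 41.8% of interaction sites.

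The labels do not say that IP and Input libraries of a number came from 1 culture. The column names of each IP and Input pair also share a last number, whose meaning is not given. Their deviations from the group means correlated at 0.181 in SCR and 0.0962 in M14KD over all 33774 sites, and at 0.189 and 0.108 over the 33356 tested sites, a set tried after the blocked results had been seen. Over 31921 sites with a mean count of at least 20 they were highest, at 0.210 and 0.117. With groups of 2, deviations mirror each other, so these are 2 values and not 4, and IP replicate 3 correlated at 0.121 with Input replicate 1 over all sites. These values do not settle the pairing. The libraries were therefore treated as sharing only numbers. If the pairs do share a culture, the interaction without the block ignores that pairing.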

Other observations

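Of the tests below, only the correction for gene span and mean level was written before its result was seen; the test of a single deciding replicate, of RNA amount, of precision, of enrichment, of an outside standard and of SCR replicate 1 were chosen after.

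A run of neighbouring genes on chromosome X held IP sites that rose. Tceal8, Tceal9, Bex2 and Arxes2 each held a higher site, and their spans lie between positions 135993820 and 136247139 of mm10. The run was picked out after its values were seen, and no test of chance independent of that choice was made. These genes and 2 tested neighbours, Bex1 inside the stretch and Bex3 at 136270253, had gene-level log2 fold changes above 0 in IP, from 0.19 (SE 0.07, Bex3) to 0.49 (SE 0.10, Tceal9), and in Input, from 0.15 (SE 0.08, Bex1) to 0.41 (SE 0.12, Tceal8). None passed at gene level by edgeR, where the lowest adjusted p was 0.155 in IP. The IP values stayed above 0 without SCR replicate 1 and without M14KD replicate 3. The Bex genes, like the Tceal genes, are related in sequence, and whether reads were shared among them was not tested.

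In the stress-response list 17 of 24 genes and in the amino acid list 17 of 22 had IP log2 fold changes below 0, with a median of -0.14 over the 46 measured genes (bootstrap 95% interval -0.21 to -0.07). Neither list's call held with an estimated correlation (adjusted p = 0.798) or with fry (adjusted p = 0.314), and these intervals resample genes as if independent. The estimated correlation also missed a simulated shift of -0.15, called in 0 of 10 simulations, so that check cannot decide here. The simulated genes were independent, so the simulations do not back the calls at the preset correlation, and fry was not simulated. A trend with gene span and mean level was argued against, since the median was -0.17 (-0.22 to -0.08) after the trend had been taken off. The median also stayed below 0 without each replicate, at most -0.11 (-0.15 to -0.02, without SCR replicate 2). Each of these fits reuses the other libraries, in which the lists had already been seen to be low. A median below 0 is therefore partly built in, and this cannot decide whether a single replicate drives the pattern. The stress-response list alone went from -0.12 to -0.03 without SCR replicate 2. A lower RNA amount of these genes is a candidate explanation: their Input median was -0.19 (-0.27 to -0.04) and their interaction median 0.0030 (-0.048 to 0.058). Whether the amounts followed Mettl14 depletion or another difference between the cultures stays open, because the groups differ in siRNA and share no replicate number.

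No site passed in the interaction, although Mettl14 counts were lower. A loss that grows with enrichment was argued against, since the gap between the highest and lowest 25% of sites was 0.0231 larger in M14KD on the log2 scale, against an SD of 0.024 between SCR replicates. Precision remains partly open: 65.1% of sites had an interval above a 2-fold fall, or 80.9% with edgeR's moderated degrees of freedom. For a 1.5-fold fall these shares were 28.3% and 50.1%. In the 25% of sites with the highest IP over Input, the shares for a 2-fold fall were 54.9% and 73.6%. The limits of 20% and 80% were set after the first value was known. An equal loss at all sites cannot be told apart from no loss, because the table held 0 rows of an outside standard. Remaining Mettl14 may also have kept sites methylated, which these counts do not test.

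Genes with longer spans had lower IP log2 fold changes, with a Spearman correlation of -0.11 across 6381 genes, and the genes with a higher site had a median span of 6.53 kb against 24.2 kb for all tested genes and 21.3 kb for genes with a lower site. SCR replicate 1 may account for the trend: without it the correlation was -0.0089, and the difference between SCR replicates 1 and 2 correlated with span at 0.18. Without SCR replicate 2 the correlation was -0.22. In Input the correlations without SCR replicates 1 and 2 were -0.011 and -0.16. With only 2 SCR libraries, which differ, these fits cannot tell which of them departs. No biological explanation was tested for this pattern.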
